A study of Mus musculus with 2 samples.

How the data were processed

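RNA was sequenced from epithelium of the gastric corpus, the acid-secreting main body of the stomach, of C57BL/6 mice that carry an Hdc-CFP transgene. In such a transgene a cyan fluorescent protein reports activity of Hdc, the gene for histidine decarboxylase, which makes histamine. One library came from sorted Hdc-CFP-positive cells (the sorted library) and 1 from corpus epithelial cells depleted of them (the depleted library). Each group therefore held 1 library. The number of mice behind each was not given in the sources used here.

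Per the labels' protocols, RNA was purified with a silica column kit and libraries were made with the TruSeq RNA kit. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.07 to the mm9 mouse genome and counted with HTSeq. The HTSeq version, its strand setting, the annotation release and the read length were not given in the sources used here. The deposited values are raw read counts per Ensembl gene identifier, not normalised, with 1 file per library. Both files listed the same 37681 gene identifiers and 5 summary rows that name no gene. Those rows stayed out of library sizes and folds. They held reads outside annotated genes (9.20% of all counted alignments in the sorted and 4.91% in the depleted library), reads matching more than 1 gene (1.45% and 1.11%) and alignments that were not unique (24.2% and 34.3%). Reads of near-identical genes and of overlapping genes are therefore missing from the counts per gene, and without a stated strand setting a gene cannot be told from an overlapping antisense partner.

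Gene symbols came from GENCODE M21, matched on the identifier, which named 32642 of the 37681 identifiers. Those without a symbol held 0.489% of the sorted and 0.392% of the depleted gene counts. M21 is built on GRCm38 while the counts were made on mm9, so no coordinates are given. Of 383 listed genes, 380 were found in the files and 325 were measured, where measured means at least 10 counts in at least 1 library. Cblif was matched through its older symbol, Gif.

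The sorted library held 10736538 counts assigned to genes and the depleted library 50928524, which is 4.74 times as many. Scaling used edgeR 4.0.16 (R 4.3.3) trimmed-mean (TMM) factors, 1.13 for the sorted and 0.882 for the depleted library, and levels are given as normalised CPM, counts scaled to a common library size. The fold of a gene is the ratio of its normalised CPM in the sorted over the depleted library. Each fold has an exact (Clopper-Pearson) 95% interval from the binomial distribution of the counts between the libraries, and each CPM an exact Poisson interval. These intervals cover counting error only. With 1 library per group there is no replicate check, and no p-value is given: every comparison is of these libraries, not of the cell populations in general. A count of 0 allows up to 3 counts, or 0.246 CPM in the sorted and 0.0668 CPM in the depleted library, and a fold against a count of 0 is a lower bound computed with that floor per library.

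A gene was counted as higher or lower when it was measured, its fold was at least 4 and its interval ended beyond 2-fold. In 34 gene lists, members were counted as higher or lower at 2-fold or more with an interval clear of 1. A list's median log2 fold, with 0.5 added to each count in proportion to library size, was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. This describes the libraries and is not a test. In these counts a ratio against 0 counts passed the fold if its interval did. Where the bound at the floor lay under the fold, this is said beside the count, or the gene was left out of it. The lists, these rules, the processing alternatives and the rule for named genes were fixed before the data were examined. That rule names 10 endocrine and mast cell genes, up to 4 members of each list with the most CPM, the 15 protein-coding genes with the most extreme interval end in each direction and the 5 genes with the most counts per library. The value of 1 gene that the rule names is not reported here. Genes outside the rule are said to have been chosen after their values were seen.

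Folds, intervals and list percentiles were tested on simulated data drawn from these libraries' means over 16996 genes, of which 200 were changed. The rule called 91% of genes changed 8-fold, 5% of those changed 3-fold and 0 of 16796 unchanged genes, and 95.7% of intervals held the true fold. The simulated counts held Poisson counting error only and were scaled by the library totals. Variation between samples and the TMM step were therefore not tested, and the 0 calls say nothing about them. As an indicator of reads shared between genes, the share of each named or listed gene's 50-base words that also occur in transcripts of another gene was computed from the M21 transcripts. Alternatives were the total without a factor, DESeq2 1.42.0 size factors, upper-quartile factors, a total without the 20 most abundant genes of each library, other count filters, a depleted library thinned to the depth of the sorted one, no interval rule and a prior of 5. A version of the lists without members sharing 15% or more of their 50-base words was added after the data were seen. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.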

Results

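The study asked where the histamine-making cells of the gastric corpus come from, and for this sorted Hdc-CFP-positive cells and sequenced their RNA beside that of the depleted corpus epithelium. The sorted library held 10736538 counts in genes and the depleted library 50928524. In the sorted library 19091 genes had at least 1 count and in the depleted library 20664. The 5 most abundant genes took 11.5% of the sorted and 19.8% of the depleted gene counts. In the sorted library these were Chga (7.26%), Pgc (1.72%), Hdc (0.992%), Pnliprp1 (0.862%) and Chgb (0.702%). In the depleted library they were Gkn1 (6.02%), Pgc (5.33%), Gkn2 (5.25%), Muc5ac (1.76%) and mt-Co1 (1.49%). Values below are normalised CPM from 1 library per group, with 95% intervals for counting error in brackets.

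Hdc itself (ENSMUSG00000027360) stood at 8750.2 CPM in the sorted and 21.2 CPM in the depleted library, a 413-fold difference [388 to 441], in the direction of the labels. The sources used here do not say whether the transgene adds to Hdc reads. The other genes of enterochromaffin-like (ECL) cells, the histamine-secreting endocrine cells of the corpus, were also higher in the sorted library where measured. Adcyap1r1, named after its value was seen, was not measured, with 0 counts in the sorted and 5 in the depleted library. Slc18a2, the vesicular monoamine transporter that loads histamine, was 290-fold higher [266 to 316] at 3402 CPM. Cckbr, the gastrin receptor, was 31.0-fold higher [28.4 to 33.9] and Sstr2, a somatostatin receptor, 6.33-fold higher [5.82 to 6.87]. All 5 measured members of the ECL list were at least 2-fold higher. Their median log2 fold of 5.24 lay at percentile 99.99 of the matched random lists. Hdc, whose reporter defined the sort, is a member, so the list was not independent of the sort.

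**Figure D1:**
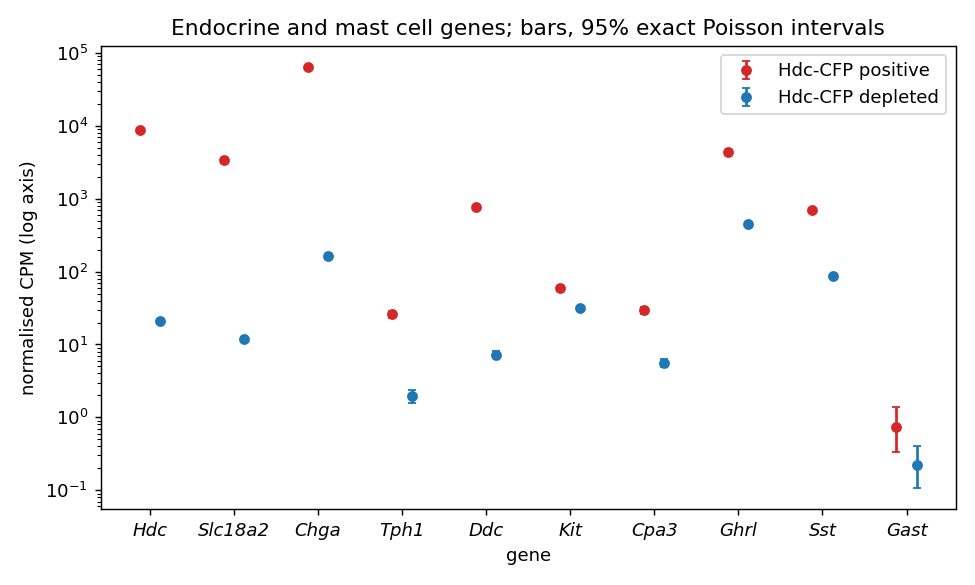
Normalised CPM (log axis) of the 10 genes named in advance in the sorted (red) and depleted (blue) library, 1 library per group; error bars are exact 95% Poisson intervals and are often smaller than the points. All 10 genes lie higher in the sorted library, from 413-fold for Hdc to 1.85-fold for Kit.

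Genes of the regulated secretory pathway were higher in the sorted library. Of 16 measured genes of endocrine granules, 16 were at least 2-fold higher, with a median log2 fold of 7.04, above all 10000 matched random lists. Chga (ENSMUSG00000021194), which encodes the granule protein chromogranin A, reached 63985 CPM against 164 CPM, a 391-fold difference [382 to 400]. Chgb was 257-fold higher [242 to 273], Cpe, a prohormone-processing carboxypeptidase, 125-fold [114 to 138], and Ptprn2 4.18-fold [4.10 to 4.26]. Among 21 measured genes of the exocytosis machinery, 20 were higher and 0 lower, with a median log2 fold of 5.92, or 5.69 with genes at 0 counts set to their bound. Rab3c was 404-fold higher [350 to 468], Snap25 209-fold [170 to 261], Cplx2 194-fold [165 to 231] and Syt7 28.1-fold [26.3 to 30.1]. The 12 measured ion channel genes of excitable cells were all at least 2-fold higher, with a median log2 fold of 6.51. The potassium channel gene Kcnh6 was 336-fold higher [257 to 446] and the calcium channel genes Cacna1h and Cacna1a 211-fold [166 to 272] and 22.7-fold [20.9 to 24.6]. Abcc8, the sulfonylurea receptor subunit, was 112-fold higher [92.7 to 137].

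Transcription factor genes of the endocrine lineage followed the same direction in 11 of 13 measured cases, with a median log2 fold of 4.72, above all 10000 random lists. Insm1 was 312-fold higher [235 to 423], St18 179-fold [151 to 215] and Rfx6 107-fold [79.3 to 148]. Foxa2, which is also active in non-endocrine gut epithelium, was only 1.42-fold higher [1.33 to 1.52] and did not reach 2-fold. Neurog3, the transient determinant of endocrine progenitors, named after its value was seen, had 1 count in the sorted and 3 in the depleted library, and a difference was not detectable at this depth. Factors of the gastric epithelium in general went the other way in 12 of 16 measured cases, with a median of -1.91. Klf4 was 11.2-fold lower in the sorted library [10.6 to 11.8], Elf3 3.81-fold [3.59 to 4.04] and Gata4 3.71-fold lower [3.54 to 3.88], while Foxa1 was 1.38-fold higher [1.32 to 1.44].

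Genes of other hormones were present in the sorted library beside Hdc. Ghrl, which encodes ghrelin, stood at 4348 CPM against 455 CPM (9.55-fold [9.39 to 9.70]). Sst, the somatostatin gene, stood at 710.4 CPM against 87.0 CPM (8.16-fold [7.86 to 8.48]). Gcg, the proglucagon gene, was 47.2-fold higher [36.1 to 62.7] at 60.9 CPM, and Pyy, with 118 counts against 1, had a ratio of 435 [76.6 to 17330.0]. Gast, the gastrin gene, was near the limit in both libraries, with 9 and 10 counts (3.32-fold [1.19 to 9.09]). Of the 8 measured genes of this list, 6 were at least 2-fold higher and 0 lower (median log2 fold 2.37, percentile 99.3). The fold of Ghrl was far below that of Chga, so the ratio of Ghrl to Chga counts was 0.0680 in the sorted and 2.78 in the depleted library.

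The labels set serotonin-expressing cells beside ECL cells, and most measured genes of serotonin metabolism were higher in the sorted library. Tph1, the tryptophan hydroxylase of non-neuronal serotonin synthesis, stood at 26.2 CPM against 1.94 CPM (13.5-fold [10.6 to 17.3]). Ddc, the decarboxylase of the next step, was 106-fold higher [95.04 to 119] at 770.6 CPM. Gch1 and Qdpr, which make and recycle the hydroxylase cofactor tetrahydrobiopterin, were 10.8-fold [9.69 to 11.98] and 9.55-fold higher [9.04 to 10.1]. Spr, of the same cofactor pathway, was 1.93-fold lower [1.76 to 2.12]. The serotonin metabolism list also holds transporter and breakdown genes, so its counts are not of synthesis alone. Not all of its members serve serotonin only, so they do not stand for a serotonin-specific set. Of its 10 measured members 8 were at least 2-fold higher and 0 lower, with a median log2 fold of 3.19, above all 10000 random lists. Slc18a1, the second vesicular monoamine transporter, chosen after its value was seen, was 277-fold higher [158 to 539]. Of the 4 measured histamine receptor and breakdown genes, 1 was at least 2-fold higher and 2 lower (median log2 fold -1.77, percentile 8.42). Hnmt, which inactivates histamine by methylation, was 9.67-fold lower [4.37 to 26.7]. Hrh1, with 1 count against 113, had a ratio of depleted to sorted of 30.6 [5.39 to 1221], Hrh3 was 31.3-fold higher [7.44 to 279.7] on 17 counts against 2, and Aoc1 did not differ beyond counting error (ratio of depleted to sorted 1.27 [0.353 to 6.87]).

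Mast cells, bone marrow-derived cells that also make histamine and in rodents serotonin, were addressed through 16 measured genes. Of these, 9 were at least 2-fold higher in the sorted library and 3 at least 2-fold lower, with a median log2 fold of 1.10 at percentile 98.8. Cpa3, the mast cell carboxypeptidase, stood at 29.3 CPM against 5.66 CPM (5.18-fold [4.40 to 6.11]). The protease genes Mcpt2, Tpsab1 and Mcpt1 were 2.30-fold [2.07 to 2.55], 2.001-fold [1.80 to 2.22] and 1.78-fold higher [1.59 to 1.98], and Kit, the stem cell factor receptor, 1.85-fold [1.69 to 2.03]. Larger folds, chosen after their values were seen, belonged to the protease genes Mcpt4 (27.9-fold [20.3 to 39.1]) and Cma1 (15.5-fold [11.6 to 21.2]). The 3 lower members, likewise named after their values were seen, were Hpgds (39.6-fold lower [18.1 to 108]), Srgn (3.99-fold [2.996 to 5.43]) and Mitf (2.11-fold [1.67 to 2.69]). Of the basophil list, 2 genes were measured: Il3ra was 2.03-fold higher [1.497 to 2.73] and Cd200r3 did not differ beyond counting error (1.11-fold [0.196 to 4.30]).

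Genes listed for leukocytes in general, not all of them active in every leukocyte type, were lower in the sorted library, with 15 of 15 measured members at least 2-fold lower and a median log2 fold of -4.56, below all 10000 random lists. Ptprc, the CD45 gene, stood at 2.30 CPM against 120.7 CPM (52.5-fold lower [36.3 to 79.1]). Tyrobp, mainly a gene of myeloid and natural killer cells, was 120.0-fold lower [55.1 to 327], Laptm5 41.0-fold [30.6 to 56.2] and Lcp1 4.40-fold [4.03 to 4.81]. The macrophage and monocyte list had the most negative median of all 34 lists, -8.59, with 11 of 11 measured members lower. Csf1r, the macrophage growth factor receptor, had 5 counts against 24469 (1327-fold lower [568.6 to 4088]), Lyz2, which shares 15.4% of its 50-base words with another gene, was 489.5-fold lower [306 to 840.5], Mrc1 306-fold [188 to 535] and C1qa 75.5-fold [58.5 to 99.2]. The 15 most depleted genes by the fixed rule included 6 members of that list (Csf1r, C1qc, C1qb, Lyz2, Adgre1 and Mrc1) and 9 others (Stab1, Vcam1, Dab2, Siglec1, Fcrls, Ctss, Axl, Apoe and Ms4a7). Of these, Vcam1 and Siglec1 had 0 counts in the sorted library and were at least 549.7-fold and 410.1-fold lower.

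T cell genes had few counts apart from Cd4 (121-fold lower [61.2 to 279.97] in the sorted library, with 3563 counts in the depleted one). Lck was 7.11-fold higher [3.60 to 14.7] on only 27 counts against 14. Cd3e, Cd3g and Cd3d, named after their values were seen, had 4 counts each in the depleted and 0 in the sorted library. Among 3 measured B and plasma cell genes, Cd79b was 11.4-fold lower [3.81 to 56.0]. Jchain was 2.54-fold higher [1.40 to 4.501] on 22 counts against 32. Pou2af1, with 2 counts against 20, had a ratio of depleted to sorted of 2.71 [0.659 to 23.9].

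**Figure D2:**
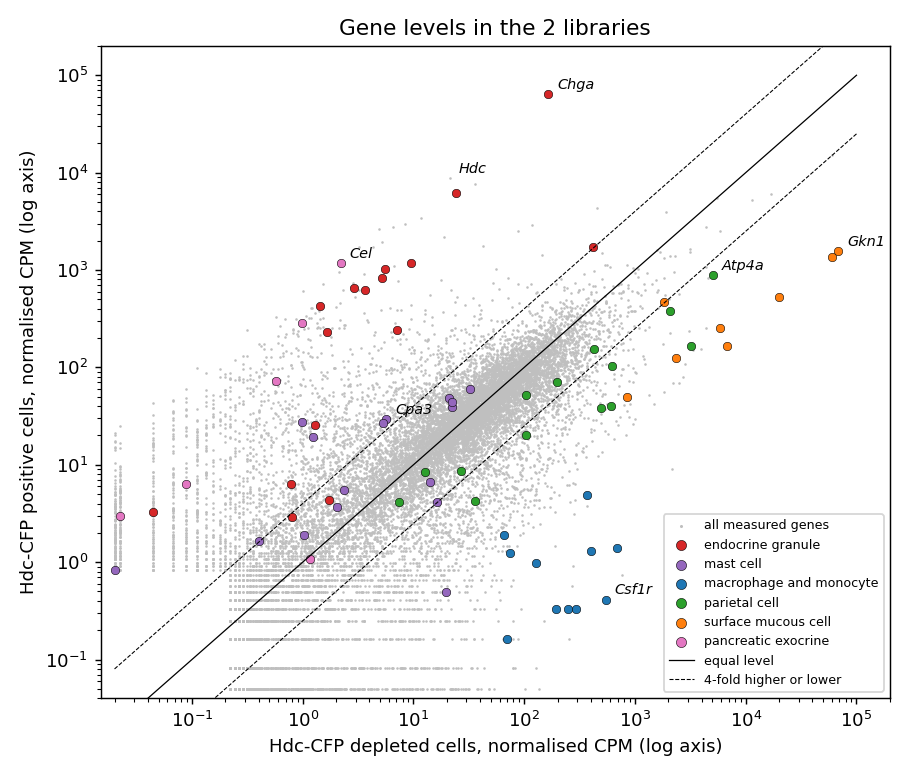
Normalised CPM of each of the 16682 measured genes in the depleted (x) and sorted (y) library, both on log axes, with members of 6 fixed lists in colour; genes with 0 counts are drawn at the low edge of the cloud. Hdc and 14 of 16 endocrine granule genes lie above the dashed 4-fold line (Scg2 and Scgn do not), macrophage genes such as Csf1r far below it.

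The corpus epithelium around the sorted cells is made of parietal, chief, surface mucous and mucous neck cells, and most measured genes of each type were at least 2-fold lower in the sorted library, by different amounts. In the surface mucous list 8 of 8 measured genes were lower, with a median log2 fold of -4.87: Gkn1 by 43.6-fold [43.0 to 44.2], Gkn2 by 44.2-fold [43.6 to 44.9], Muc5ac by 37.5-fold [36.5 to 38.4] and Mucl3 by 40.6-fold [38.8 to 42.4]. In the parietal list 12 of 14 were at least 2-fold lower, with a median of -2.41. Atp4a and Atp4b, the subunits of the acid pump, were 5.71-fold [5.60 to 5.82] and 5.54-fold lower [5.37 to 5.70] and still stood at 886 and 376 CPM. Clic6 was 6.09-fold [5.76 to 6.45] and Car2, which encodes carbonic anhydrase, 19.0-fold lower [18.2 to 19.9]. Of 7 measured chief cell genes, 4 were lower and 0 higher by 2-fold (median -1.99). Pgc, the pepsinogen C gene, stood at 15187 CPM against 60505 CPM (3.98-fold lower [3.97 to 4.003]), Chia1 was 5.51-fold lower [5.40 to 5.62] and Cblif, which encodes intrinsic factor, 1.74-fold lower [1.69 to 1.79]. Rab3d was 1.28-fold lower [1.23 to 1.33], a direction that turns without a scaling factor, and Bhlha15, named after its value was seen, 1.90-fold higher [1.65 to 2.18]. Of 4 mucous neck genes, 3 were lower: Tff2 by 17.4-fold [16.8 to 18.1], Muc6 by 4.42-fold [4.32 to 4.53] and Aqp5 by 2.64-fold [1.92 to 3.70], with Gkn3 at 1.61-fold lower [1.45 to 1.79]. Tff1 and Lipf, named after their values were seen, were listed at 0 in both libraries. Tff1 is a typical gene of surface mucous cells, the cause of its 0 could not be settled from the files, and neither 0 shows absence of expression.

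Tuft cells, rare chemosensory cells of the same epithelium, were represented by 16 measured genes, of which 14 were lower and 2 higher in the sorted library. With genes at 0 counts held to their bound, 12 were at least 2-fold lower, since Hmx2 and Gfi1b, named after their values were seen, had bounds of 1.45-fold and 1.54-fold. The median log2 fold was -4.73, or -3.27 with genes at 0 counts set to their bound, and below all 10000 random lists. Avil was 38.4-fold lower [29.4 to 51.0], Alox5 8.25-fold [5.40 to 13.2] and Alox5ap 7.44-fold [4.998 to 11.6], and Ptgs1, with 0 counts in the sorted library, at least 121.4-fold lower. The general epithelial list was mixed, with 6 of 9 lower and 2 higher (median -1.52). Krt19 was 22.1-fold [21.1 to 23.1], Krt8 9.14-fold [8.79 to 9.49], Cldn18 2.87-fold [2.79 to 2.96] and Cdh1 2.61-fold lower [2.55 to 2.67]. Krt8 shares 29.7% of its 50-base words with a pseudogene. The 2 higher members, named after their values were seen, were Cldn7 (40.9-fold [31.8 to 53.3]) and Krt7 (27.7-fold [25.4 to 30.3]), and Epcam, also named then, was 1.98-fold higher [1.91 to 2.04].

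**Figure D3:**
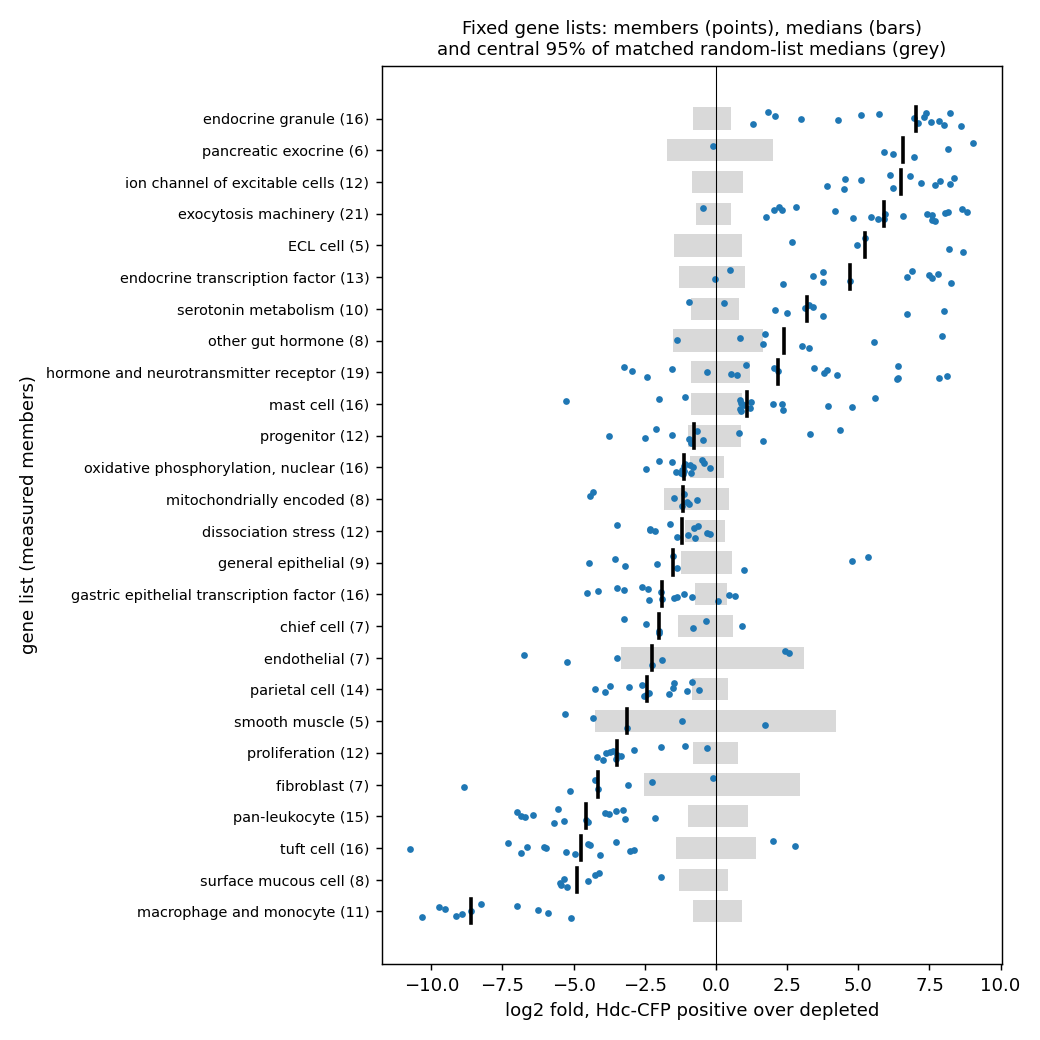
Log2 fold (sorted over depleted) of each measured member (points) of the lists with at least 5 measured members, except the sex-linked list, with the list median (bar) and the central 95% of medians of matched random lists (grey). Medians run from -8.59 for macrophage genes to 7.04 for endocrine granule genes.

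Proliferation genes were lower in the sorted library in 11 of 12 measured cases, with a median log2 fold of -3.49, below all 10000 random lists. Mki67 was 15.6-fold [13.4 to 18.2], Top2a 11.3-fold [9.82 to 13.1] and Plk1 7.44-fold lower [6.40 to 8.70]. Mcm2 was 1.25-fold lower [1.12 to 1.39], a direction that turns without a scaling factor. Progenitor genes were mixed, with 3 of 12 higher and 4 lower (median -0.78, percentile 4.99). Smoc2 was 20.8-fold [18.0 to 24.1] and Lrig1 3.13-fold higher [2.99 to 3.27], while Prom1 was 1.60-fold [1.51 to 1.70] and Sox9 1.91-fold lower [1.72 to 2.14].

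Receptors for hormones and neurotransmitters were higher in 12 of 19 measured cases and lower in 4 (median log2 fold 2.19, percentile 99.9). Vipr1, a receptor of vasoactive intestinal peptide, was 19.1-fold [16.9 to 21.8], Ffar2, a short-chain fatty acid receptor, 87.2-fold [60.2 to 131] and Gipr 87.3-fold higher [54.6 to 149]. Glp1r was 5.34-fold lower [4.26 to 6.80].

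Apart from the leukocyte and macrophage lists described above, lists for tissues outside the corpus epithelium held low levels, with 1 exception. Measured fibroblast genes summed to 1.23 CPM in the sorted and 19.4 CPM in the depleted library, and 5 of 7 were lower: Col3a1, with 0 counts, by at least 32.9-fold, Dcn by 8.95-fold [3.41 to 33.3], and Col1a1 and Col1a2, with 1 and 2 counts, at ratios of depleted to sorted of 42.3 [7.48 to 1681.5] and 19.5 [5.31 to 163]. Of 7 endothelial genes 4 were lower and 2 higher. Esam was 5.39-fold higher [4.39 to 6.64] and Vwf, on 22 counts against 13, 6.24-fold higher [3.01 to 13.5]. Pecam1 was 4.81-fold lower [2.38 to 11.4], while Tek, with 2 counts, had a ratio of depleted to sorted of 12.2 [3.28 to 102.3]. Of 5 smooth muscle genes 3 were lower and 1 higher. Acta2 was 9.15-fold lower [3.49 to 34.1] and Myh11, on 20 counts against 22, 3.35-fold higher [1.74 to 6.44]. Actg2, with 0 counts in the sorted library, was at least 2.71-fold lower, and Tagln, which shares 58.4% of its 50-base words with another gene, 2.30-fold lower [1.69 to 3.21]. All 3 measured neuron and glia genes were higher, among them Elavl4 by 277-fold [107 to 1022] and Tubb3 by 3.46-fold [1.59 to 7.47]. From the red blood cell list only Alas2 was measured, with 3 counts against 16.

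The exception was the list of pancreatic exocrine enzymes, fixed as a check for neighbouring tissue. Of 6 measured members 5 were higher in the sorted library, with a median log2 fold of 6.58, above all 10000 random lists. Cel, the bile salt-activated lipase gene, stood at 1172 CPM against 2.20 CPM (532-fold [436 to 654.6]), Prss2, a trypsinogen gene, was 292-fold [217 to 402], Cela2a 127-fold [85.8 to 195] and Ctrb1 71.9-fold higher [27.0 to 270.5]. Cela2a shares 15.6% of its 50-base words with another gene. The other 5 listed genes, named after their values were seen, were not measured: Cpa1 had 0 counts, Pnlip 3, Amy2a5 2 and Cpb1 and Ctrl 4 each in the sorted library.

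By the rule over all 16682 measured genes, 2272 were at least 4-fold higher and 1927 at least 4-fold lower in the sorted library, and 12483 were neither. Of the lower genes, 47 had 0 counts in the sorted library and a bound under 4-fold. The 15 protein-coding genes at the top of the higher set included Hdc, Chga, Rab3c and Cel. They also included Gc (540-fold [472 to 619.5]) and Vtn (424.5-fold [379 to 478]), which encode the plasma proteins vitamin D-binding protein and vitronectin. Rbpjl, which encodes a transcription factor of pancreatic acinar cells, was 600.3-fold higher [448 to 824], Insrr, an insulin receptor-related receptor, 535-fold [455 to 634], and the potassium channel subunit gene Kcnmb2 566-fold [385 to 867]. Nphs1 and Kirrel2, known from the slit diaphragm of the kidney, were 885-fold [378 to 2731] and 469.9-fold higher [370.3 to 606]. The remaining members were Col11a1 (777.5-fold [463 to 1424]), Try5 (447-fold [366 to 553]), Ccn3 (373-fold [328 to 426]) and Pappa2 (358-fold [323 to 397]). Try5 shares 47.6% of its 50-base words with another trypsin gene and its value is uncertain.

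Of 16 nuclear genes listed for oxidative phosphorylation, 10 were at least 2-fold lower in the sorted library (median log2 fold -1.12, percentile 0.62). Atp5b was 2.35-fold [2.31 to 2.40], Atp5a1 2.23-fold [2.18 to 2.27], Cox4i1 2.31-fold [2.22 to 2.40] and Cs, which encodes citrate synthase, an enzyme of the citric acid cycle and not of the respiratory chain, 3.99-fold lower [3.81 to 4.19]. Genes of parietal cells, which are rich in mitochondria, were also lower in the sorted library, 12 of 14 by at least 2-fold (median log2 fold -2.41). Of 8 measured mitochondrially encoded genes 4 were at least 2-fold lower, but the median log2 fold of all 8, -1.16, lay within the matched random lists, at percentile 15.3. The 4 were mt-Co1 (2.78-fold [2.76 to 2.80]), mt-Cytb (2.18-fold [2.17 to 2.20]), mt-Nd1 (2.28-fold [2.26 to 2.31]) and, named after its value was seen, mt-Nd4 (2.04-fold [2.01 to 2.07]), with mt-Nd5 at 1.59-fold lower [1.57 to 1.60]. Without a scaling factor Atp5b, Atp5a1, Cox4i1, mt-Cytb, mt-Nd1 and mt-Nd4 stay lower but by less than 2-fold, so these counts at 2-fold depend on the scaling. mt-Co2 (bound 1.45-fold lower, so not counted) and mt-Atp6, named after their values were seen and at 0 counts in the sorted and 16 and 15 in the depleted library, share 100% and 99.5% of their 50-base words with other annotated genes, and mt-Co1 and mt-Nd4 share 51.1% and 62.2%. Of 12 immediate-early and heat shock genes, which respond to tissue dissociation, 6 were at least 2-fold lower in the sorted library. These include Hspa1a and Hspa1b, named after their values were seen, which share 66.3% and 62.3% of their 50-base words and are uncertain. Fos was 1.67-fold [1.64 to 1.70], Jun 1.97-fold [1.92 to 2.01] and Fosb 2.61-fold lower [2.54 to 2.68]. Egr1 was 1.24-fold lower [1.21 to 1.26], a direction that turns without a scaling factor.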

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

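Of all counted alignments 65.1% in the sorted and 59.6% in the depleted library were assigned to a gene, so in total a lower share of the sorted library fell outside the counts per gene. The 3 summary rows that held any reads differed in direction. Reads outside annotated genes made up 9.20% of the sorted [9.19 to 9.21, Wilson 95% interval] and 4.91% of the depleted library [4.90 to 4.91]. Reads that matched more than 1 gene made up 1.45% [1.45 to 1.46] and 1.11% [1.11 to 1.12]. The third row, alignments that were not unique, was lower in the sorted library, at 24.2% against 34.3%. The intervals cover counting error only, and no explanation was tested.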

How the results depend on the processing

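Counts of genes past the 4-fold rule stayed within 1.5 times of 2272 higher and 1927 lower genes under the 8 alternatives run on them. Higher genes ranged from 1574 with a 50-count filter to 2629 without a scaling factor, and lower genes from 1554 without a factor to 2419 without the interval rule. Without a factor, the 2272 higher genes were all among the 2629, and the 1554 lower genes were all among the 1927. Scaling shifts all folds together: the median log2 fold of all measured genes was -0.05 with TMM factors, 0.31 without a factor and 0.16 with a total that leaves out the 20 most abundant genes of each library. The cause of the scaling differences was not tested further. Without a factor the Hdc fold was 531 and the median log2 folds were 7.40 for endocrine granule, 1.46 for mast cell, -4.20 for pan-leukocyte and -2.05 for parietal genes. Without the 20 most abundant genes they were 479 for Hdc, 1.31 for mast cell and -2.20 for parietal genes. A prior of 5 moved the tuft cell median to -3.54; 5 of its members had 0 counts in the sorted library, where the prior sets the value. These 5 list medians kept their sign under every alternative run. Among 154 named genes, 573 of 770 values under other scalings or equal depth lay within the counting interval of the fold, 194 outside it with the same sign, and 3 turned: without a factor the log2 folds were 0.0073 for Rab3d, 0.042 for Mcm2 and 0.059 for Egr1. Leaving out members with shared sequence, an alternative chosen after seeing the data, moved none of the 5 medians beyond counting error. No paired analysis was possible because each group held 1 library, and leaving out a replicate or splitting the libraries was not possible for the same reason. Depth limits the sorted library most: 3 counts there correspond to 0.246 CPM against 0.0668 CPM in the depleted one.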

Other observations

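Single genes outside the fixed lists, chosen after their values were seen, also differed between the libraries, and they do not stand for a gene group, as no list of such genes was tested. Among genes of plasma proteins, besides Gc and Vtn, Agt, the angiotensinogen gene, was 164-fold higher [146 to 185], Ahsg 347-fold [265 to 464], Ambp 96.9-fold [65.1 to 151], Ttr 13.8-fold [13.2 to 14.5] and Cpn1 7.17-fold [6.87 to 7.48]. The imprinted genes Peg3 and Meg3 were 115-fold [108 to 124] and 253-fold higher [216 to 297]. Mboat4, whose product acylates ghrelin, was 284-fold higher [215 to 382] although Ghrl was 9.55-fold higher, and the ratio of Ghrl to Mboat4 counts was 13.5 in the sorted and 401 in the depleted library. Th, which encodes tyrosine hydroxylase, had 220 counts against 2 (ratio 406 [111 to 3370.4]), and the homeobox genes Lhx5 and Nkx6-2 were 117-fold [96.5 to 144] and 24.2-fold higher [22.1 to 26.5].

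Some genes of detoxifying enzymes, picked in the same way, were lower in the sorted library. Ptgr1 was 33.4-fold lower [31.4 to 35.6], Nqo1 32.9-fold [30.6 to 35.6], Aldh3a1 32.2-fold [30.1 to 34.5], Adh7 27.2-fold [24.4 to 30.5], Gsta4 26.5-fold [25.1 to 28.0], Gsto1 25.2-fold [24.1 to 26.4] and Mgst3 21.5-fold [19.7 to 23.4], and Nfe2l2, a regulator of such genes, 9.06-fold lower [8.62 to 9.53]. Il33, an epithelial cytokine gene, was 37.5-fold [32.2 to 44.0] and Cd74, a gene of antigen presentation, 40.9-fold lower [36.1 to 46.5]. Both libraries held Xist (691 CPM in the sorted and 414 CPM in the depleted) and the Y-linked genes Ddx3y (71.9 and 49.5 CPM), Eif2s3y (51.9 and 46.9 CPM) and Uty (34.7 and 25.9 CPM), and 0 of the 5 sex-linked genes differed by 2-fold. All tests below were chosen after the results were seen.

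Of the pancreatic enzyme list 5 of 6 measured genes were higher in the sorted library, as were Rbpjl (600.3-fold), Pnliprp1 (213-fold [203 to 224] at 7603 CPM) and Ptf1a (263-fold [182 to 393]), whereas Try4, uncertain because it shares 65.6% of its 50-base words with another gene, did not differ beyond counting error (0.922-fold [0.461 to 1.72]) and Pnliprp2 and Pla2g1b were 1.26-fold [1.15 to 1.39] and 4.03-fold lower [3.96 to 4.11] (Ptf1a, Try4, Pnliprp2 and Pla2g1b were chosen after their values were seen). Pancreatic acinar cells or their RNA in the sort stay open. Of the 11 listed acinar genes, 5 were at or under 4 counts in the sorted library while Cel had 14273. Of the 5, Amy2a5 shares 53.5% of its 50-base words and Cpa1 was at 0 in both libraries for an unsettled cause. That leaves Pnlip with 3 counts and Cpb1 and Ctrl with 4 each. The limit of 4 counts was set after these values were seen, and the test asked for at least 4 such genes, so it does not decide the question. Of Cel, Prss2, Ctrb1 and Pnliprp1, none shares more than 7.83% of its 50-base words with another gene. For Try5, Cela3b and Cela2a up to 47.6% is shared. Alignments that were not unique stayed out of the counts per gene, so shared words by themselves remove reads and do not raise a count. The shares therefore do not decide whether reads of a paralog added to these counts. Reads placed on a paralog with mismatches were not examined, and for all of these genes that source stays open. Transcription of these genes in endocrine cells of the gate was not tested.

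Of 16 measured mast cell genes 9 were at least 2-fold higher in the sorted library, 1 of them, Tpsab1, barely, and 3 lower, while 15 of 15 genes listed for leukocytes in general were lower. The depleted library also held macrophage and monocyte genes at a summed 3075 CPM, against 13.2 CPM in the sorted one. Which leukocyte type the reads of the 15 genes came from was not resolved. Their lower level therefore does not show fewer mast cells in the sort. Carry-over in proportion to the depleted cells is argued against, because it cannot raise a gene above its depleted level and 9 measured mast cell genes were at least 2-fold higher. Among those 9, at most 5.48% of 50-base words were shared with another gene. Shared words by themselves remove reads and do not raise a count, so this share does not decide whether reads of a paralog were added. Reads placed on a paralog with mismatches were not examined. Mast cells in the gate stay open. They make Hdc, but whether the CFP transgene is active in them is not given in the sources used here. The median count of Ptprc, Fcer1g and Srgn was 7.84% of that of Cpa3 in the sorted library. No mast cell profile was used here to say what share mast cells would need. Transcription of the mast cell genes in Hdc-CFP-positive cells of other types was not tested.

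Parietal genes were lower in the sorted library by less than surface mucous genes were, by list medians of -2.41 and -4.87. Carry-over in proportion to the depleted cells, as cells or as free RNA, is argued against as the whole source: the surface mucous median was lower than the parietal one by a log2 difference of -2.45, with interquartile ranges of -5.37 to -4.21 and -2.95 to -1.49. Whole parietal cells in the gate would lower all parietal genes by 1 factor. Their interquartile range was 1.46 on the log2 scale, and as several of these genes are not restricted to parietal cells, this cannot be told apart from uneven transcription in the sorted cells. A difference in depth along the gland between the cells carried over, and low transcription of these genes in the sorted endocrine cells, were not tested.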
